A study of Homo sapiens with 12 samples.

How the data were processed

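Gene expression was measured on 12 Affymetrix arrays in circulating mononuclear cells of volunteers who breathed filtered air or ultrafine carbon particles through a mouthpiece. Blood was drawn before exposure (0 h) and 24 h after it, and each of the 4 groups of exposure and time held 3 arrays. The authors extracted RNA with TRIzol LS, amplified and biotin-labelled it, and hybridised 1 array per sample. The deposited values are log2 expression per probe set, which the submitters' processing notes attribute to RMA and Partek 6.4; the settings of RMA were not given. The log base was inferred from the range of the values and the equal array means. No raw intensities were used here.

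Of 54675 deposited probe sets, 62 control probe sets and 95 probe sets of sex-linked genes (XIST and Y-linked) were left out, which left 54518. Probe sets with a mean over the 12 arrays below the median of all means (log2 5.02) were not tested, which left 27259. The platform table named 1 gene for 41097 probe sets, several for 1801 and none for 11777. Only probe sets naming 1 gene were named or entered into gene lists, and 41043 of them were matched to current symbols by gene identifier.

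An exposure session was defined as the pair of arrays with the same exposure and number, because the study took a sample before and a sample after exposure from each person. As a check of this pairing, arrays were correlated after removal of each probe set's mean within each group of exposure and time. Among the arrays of the same exposure at the other time, 12 of 12 arrays matched their own session best. Arrays of the other exposure were not candidates in this check. Whether number 1 of the filtered air sessions was the same person as number 1 of the particle sessions was not given. The main model, set without that knowledge, did not pair numbers across exposures. In a check for mixed-up samples, 0 of 6 sessions held arrays that disagreed.

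Linear models were fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with session as a fixed block and 4 residual degrees of freedom. The contrasts were 24 h minus 0 h in the particle sessions, the same in the filtered air sessions, and the particle change minus the filtered air change, which tests the difference itself. Particles were also compared with filtered air at 0 h and at 24 h by group means with session as a random block (within-session correlation 0.48, 8 residual degrees of freedom). Probe sets were called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. All errors given after ± for changes are standard errors of the limma model, and group levels are mean ± SD over 3 arrays. The standard errors rest on 1 residual spread per probe set, pooled over both exposures and moderated across probe sets. They do not give the spread of the 3 sessions of a comparison and can be far from it. For GVINP1 in the particle sessions the standard error was 0.32, while the SD of the 3 session changes was 1.09. The limma p values of single probe sets measure the spread between these samples and these sessions. The number of arrays limits the precision.

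The 24 gene lists were NRF2 antioxidant, aryl hydrocarbon receptor, heat shock, unfolded protein response, NF-kB inflammation, interferon-stimulated, immediate early, glucocorticoid-induced, circadian clock, p53 and DNA damage, adhesion and trafficking, coagulation and fibrinolysis, oxidative phosphorylation, ribosomal proteins, proliferation, and the markers of T cells, cytotoxic and NK cells, B cells, plasma cells, monocytes, dendritic cells, neutrophils, platelets and erythroid cells. They held 449 members, of which 355 were tested, with 1 probe set per gene (the brightest) and 12302 genes as background. Lists were tested with camera from limma at its preset correlation of 0.01, adjusted over the 24 lists. They were tested again with a correlation estimated per list and with fry. At the preset correlation the camera p values rest mainly on the spread across genes taken as nearly independent, not on that between sessions. Members were adjusted over all probe sets and over the list alone.

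The samples, lists, tests, alternatives and the rule for named genes were set before the data were examined. The rule took up to 12 genes per direction with the largest change among called probe sets that moved the same way in all 3 sessions (for the difference, all 3 particle changes on one side of all 3 filtered air changes). Places not filled by called probe sets went to probe sets with an unadjusted p below 0.05 under the same rule on sessions. For the comparisons at 1 time the rule took 5 per direction. Of each list, the 4 tested members with the smallest p could be named too.

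The models were tested on simulated data of the same size (3 runs of 27259 probe sets with independent noise). A 2-fold change was recovered for 281 of 300 probe sets in the particle contrast and 164 of 300 in the difference, and a 4-fold change for 300 and 297 of 300. There were 42 and 27 false calls over the 3 runs. In 20 simulated sets, camera called 1 of 480 unchanged lists and found a list raised by 0.3 log2 in 20 of 20. The simulated genes were not correlated, so that camera was not tested there on correlated members.

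Alternatives were a second quantile normalization, centring of arrays on their medians, no filter, a filter keeping the brightest 25% of probe sets, an intensity trend with robust moderation (for lists the trend alone, as camera has no robust form), array weights, leaving out each session, other blocks, other thresholds, an estimated correlation, fry and another probe set per gene. Fits of sessions numbered 2 and 3 only, and with the actin 3'/5' difference as a covariate, were added after the data were seen. Figures were drawn with Python 3.11.15.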

Results

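The data were 12 expression profiles of circulating mononuclear cells, the lymphocytes and monocytes of blood, from 6 exposure sessions. In 3 sessions a volunteer breathed filtered air and in 3 sessions ultrafine carbon particles at 50 ug/m3, each for 2 h with 4 exercise periods of 15 min at a ventilation of 20 L/min/m2. Each session gave 1 array at 0 h and 1 at 24 h. The array means were equal at log2 5.70, the array medians lay between 4.98 and 5.08, and the correlations between arrays lay between 0.941 and 0.991.

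Arrays differed in ways that the groups did not explain. The 4 arrays of the sessions numbered 1, in both exposures, lay at -52.2 to -34.2 on the first principal component (39.6% of the variance), against -11.6 to 33.1 for the others. In those 4 arrays the actin 3' probe sets exceeded the 5' probe sets by log2 3.72 to 5.15, against 3.29 to 4.06 in the other arrays. The 24 h array of filtered air session 2 stood apart, with an interquartile range of log2 2.31 against 2.50 to 2.79 and a mean correlation with other arrays of 0.954 against 0.965 to 0.973. Between 0 h and 24 h, 5100 probe sets differed by at least 1.5-fold in that session, 4365 of them lower, against 595 to 1926 in each of the other sessions.

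**Figure D1:**
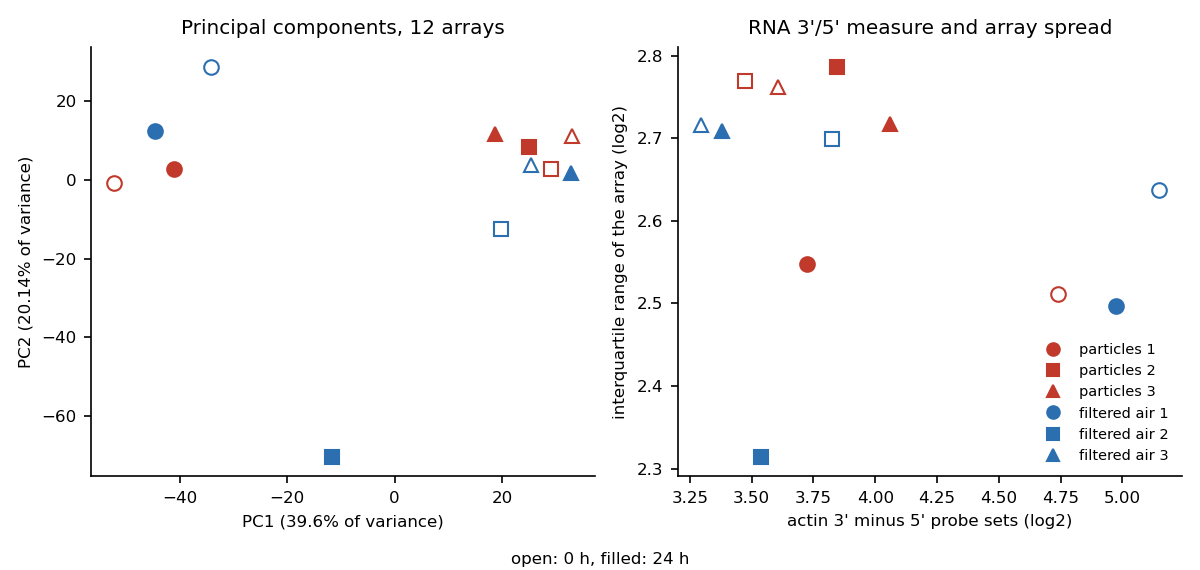
The left panel plots the first against the second principal component of the 12 arrays, and the right panel plots each array's interquartile range (log2) against its actin 3' minus 5' difference (log2); colours give the exposure, shapes the session number, and open and filled symbols 0 h and 24 h. The 24 h array of filtered air session 2 lies at -70.4 on the second component, against -12.5 to 28.9 for the other arrays.

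The first comparison asked which transcripts differed between 0 h and 24 h in the 3 particle sessions. As groups, the markers of T cells, of cytotoxic and NK cells and of B cells fell, and monocyte, platelet, interferon-stimulated and glucocorticoid-induced transcripts rose. None of these lists was called with a correlation estimated per list (adjusted p = 0.57 to 0.60 with an estimated correlation). Erythroid transcripts, the products of red cell precursors and reticulocytes, fell by the same test (adjusted p = 0.57 with an estimated correlation). These were shifts of whole lists by camera, while 0 of 27259 single probe sets passed limma's adjusted threshold.

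All 17 tested cytotoxic and NK markers were lower, and the list fell with a median log2 change of -0.21 (camera adjusted p = 2.07e-07). The values with the smallest p were those of GNLY, the granule protein granulysin, at -0.63 ± 0.19, CST7 at -0.50 ± 0.19 and TBX21, the transcription factor T-bet, at -0.17 ± 0.11. All 19 tested T cell markers were lower, and the list fell with a median of -0.16 (adjusted p = 0.000125); the costimulatory receptor CD28 stood at -0.26 ± 0.14 and CD8B at -0.26 ± 0.17. Of 13 B cell markers 10 were lower, and the list fell with a median of -0.11 (adjusted p = 0.021), with VPREB3 at -0.31 ± 0.15 and the kinase BLK at -0.62 ± 0.32. By 1 of its 4 tested probe sets, the B cell marker MS4A1 was higher in all 3 particle sessions, at 0.59, 0.39 and 0.13. None of these 3 lists was called with an estimated correlation, at adjusted p = 0.57 with an estimated correlation for the cytotoxic and T cell lists and adjusted p = 0.60 with an estimated correlation for B cells. The cytotoxic median was -0.03, 0.02 and -0.72 in particle sessions 1, 2 and 3. Without particle session 3 the cytotoxic and NK markers had a median of -0.02 (adjusted p = 0.86) and the T cell markers one of -0.08 (0.22), and without particle session 2 the B cell markers had one of 0.00 (0.56) and the T cell markers one of -0.09, still called. Without particle session 1 the B cell median was -0.17, still called.

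Of 18 monocyte markers 14 were higher, and the list rose with a median of 0.08 (adjusted p = 0.00516; adjusted p = 0.60 with an estimated correlation). The scavenger receptor CD163 stood at 0.31 ± 0.14, the receptor CSF1R at 0.33 ± 0.16 and the lectin CLEC4E at 0.43 ± 0.20. Of 17 platelet markers 13 were higher, and that list rose with a median of 0.16 (adjusted p = 0.00335; adjusted p = 0.60 with an estimated correlation), with the integrin ITGB3 at 0.31 ± 0.16 and PF4V1 at 0.44 ± 0.30. Without particle session 1 the median of the monocyte markers was larger, at 0.15, but the list was not called (adjusted p = 0.11); without particle session 3 it was 0.01 (0.66), and without particle session 2 it was 0.17, still called. The platelet markers had a median of 0.11 without particle session 2 (adjusted p = 0.35) and of 0.28, still called, without particle session 1.

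Interferon-stimulated genes, the antiviral program downstream of interferon receptors, rose with 21 of 23 members higher and a median of 0.10 (adjusted p = 6.56e-06; adjusted p = 0.57 with an estimated correlation). Their medians were 0.16, 0.01 and 0.22 in particle sessions 1, 2 and 3, and the list stayed called without session 1 (median 0.15) and without session 2 (0.21). IFI44L stood at 0.35 ± 0.12, the sialic acid receptor SIGLEC1 at 0.41 ± 0.16 and OAS3, a synthase of the RNase L pathway, at 0.30 ± 0.15. Glucocorticoid-induced genes rose with 11 of 14 members higher and a median of 0.16 (adjusted p = 0.00165; adjusted p = 0.57 with an estimated correlation). The members with the smallest p were the adenosine receptor ADORA3 at 0.53 ± 0.19, CD163, which the monocyte list also held, and the decoy receptor IL1R2 at 0.69 ± 0.36. Immediate early genes, the first responders to growth and stress signals, rose with 14 of 18 higher and a median of 0.08 (adjusted p = 0.014; adjusted p = 0.60 with an estimated correlation), with FOS at 0.56 ± 0.32 and EGR1 at 0.46 ± 0.32. The immediate early medians were -0.01, -0.18 and 0.26 in particle sessions 1, 2 and 3, below 0 in 2 of 3 sessions. The unfolded protein response list rose with 12 of 17 higher and a median of 0.08 (adjusted p = 0.0398; adjusted p = 0.57 with an estimated correlation), with XBP1 at 0.37 ± 0.16 and the chaperone HSPA5 at 0.24 ± 0.16. Without particle session 3 the median was 0.03 for the glucocorticoid-induced list (adjusted p = 0.25), 0.03 for the immediate early list (0.80) and 0.02 for the unfolded protein response (0.35). The last also lost its call without particle session 2 (median 0.03, adjusted p = 0.35), filtered air session 2 (0.08, 0.0557) or filtered air session 3 (0.08, 0.0684), where its median did not move. Without particle session 2 the glucocorticoid-induced median was 0.25, and without particle session 1 the immediate early median was 0.14, both still called.

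Of 8 erythroid markers 7 were lower, and the list fell with a median of -0.37 (adjusted p = 1.24e-06; adjusted p = 0.57 with an estimated correlation). ALAS2, which starts heme synthesis in red cell precursors, stood at -0.80 ± 0.25, HBB, the beta globin, at -0.55 ± 0.20 and BPGM at -0.29 ± 0.11. The list medians were -0.54 and -0.47 in particle sessions 1 and 2 and 0.13 in particle session 3, and without particle session 2 the median of the list was -0.23, still called.

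Over all tested probe sets, 20.42% went the same way in the 3 particle sessions, where chance gives 25%. The genes named by the rule did so by choice and did not pass the adjusted test of limma (adjusted p of 0.82 or more). The highest value was that of ZNF12, a zinc finger protein, at 0.93 ± 0.12, or 1.91-fold, with 0.92, 0.78 and 1.10 in the 3 sessions. It went from log2 5.78 ± 0.11 at 0 h to 6.71 ± 0.24 at 24 h. PAPSS2, which makes the sulfate donor of the cell, stood at 0.87 ± 0.24, the folate receptor FOLR1 at 0.67 ± 0.26, the cell cycle inhibitor CDKN1C at 0.59 ± 0.18 and DUSP6, a phosphatase of ERK kinases, at 0.53 ± 0.16. CPM, CREB5, APC, ZNF366, IFI44, ADORA3 and SRGAP2 lay between 0.53 and 0.58. The lowest values were those of the pseudogene GVINP1 at -1.16 ± 0.32 and of CYCS, cytochrome c, at -1.12 ± 0.18. GVINP1 had -0.56, -2.42 and -0.50 in the 3 sessions, and CYCS -0.90, -1.30 and -1.15. CARD8-AS1, ANKRD42-DT, THRAP3, NKTR, PRPF19, HBB, CLN6, CAND1, B2M and PCNP lay between -0.94 and -0.68, HBB by another of its probe sets than that used for the erythroid list. For B2M, 1 of 3 tested probe sets had this sign, for GVINP1 1 of 2, for NKTR 2 of 7, for APC 2 of 4, and for the other genes most of them. GVINP1, CYCS and PCNP had a group mean below the filter of log2 5.02.

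In the particle comparison limma called 0 probe sets, and 505 had an unadjusted p below 0.05 (229 higher, 276 lower) where chance gives 1363 of independent probe sets; no other tool was run on single probe sets. Without particle session 3 the split was 270 higher and 134 lower, and 4 lists instead of 10 were called. The number with an unadjusted p below 0.05 was 802 without filtered air session 2 and 1052 without particle session 1. With array weights it was 1537, above the number that chance gives. With 3 sessions the median standard error was 0.14 log2, and 0 list members passed adjusted over the list alone or over all genes. The directional test of fry called 0 of the 10 lists (adjusted p = 0.87 for each).

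The second comparison asked the same of the 3 filtered air sessions, which shared the exercise, the mouthpiece and the 24 h interval. As groups, immediate early and adhesion transcripts fell, and B cell and erythroid transcripts rose. None of the 4 lists was called with a correlation estimated per list (adjusted p = 0.79 with an estimated correlation for each). The genes with the largest values included CDKN1C and SLC30A1 on the lower side and globin genes on the higher side, but 0 of 27259 single probe sets passed the adjusted test.

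Of 18 immediate early genes 16 were lower, and the list fell with a median of -0.26 (adjusted p = 0.0287; adjusted p = 0.79 with an estimated correlation). KLF4, a transcription factor of monocytes, stood at -0.62 ± 0.18, the phosphatase DUSP2 at -0.46 ± 0.20 and JUNB at -0.41 ± 0.19. The list medians were -0.09, -0.73 and -0.08 in filtered air sessions 1, 2 and 3, and session 2 held the array that stood apart; without it the immediate early list had a median of -0.07 (adjusted p = 0.38), and without filtered air session 3 one of -0.38 (0.0533). Of 18 adhesion and trafficking genes 17 were lower, and the list fell with a median of -0.16 (adjusted p = 0.00652; adjusted p = 0.79 with an estimated correlation). The members with the smallest p were the integrin chains ITGB2 at -0.60 ± 0.20, ITGAL at -0.70 ± 0.24 and ITGAX at -0.52 ± 0.19 and their ligand ICAM1 at -0.36 ± 0.12. The adhesion and trafficking medians were -0.11, -0.32 and -0.16 in the 3 sessions, and without filtered air session 3 the median was -0.24 (adjusted p = 0.0505).

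Of 13 B cell markers 10 were higher, and the list rose with a median of 0.19 (adjusted p = 0.00132; adjusted p = 0.79 with an estimated correlation). VPREB3 stood at 0.54 ± 0.15, FCRLA at 0.34 ± 0.12 and CD79A, part of the B cell receptor, at 0.40 ± 0.16. The B cell markers had medians of 0.39, -0.11 and 0.24 in the 3 filtered air sessions, and without filtered air session 1 the median of the list was 0.07 (adjusted p = 0.26); without sessions 2 and 3 in turn it was 0.31 and 0.11, still called. All 8 erythroid markers were higher, and the list rose with a median of 0.31 (adjusted p = 0.00034; adjusted p = 0.79 with an estimated correlation), at 0.35, 0.44 and 0.08 in the 3 sessions. HBB stood at 1.11 ± 0.20 and the delta globin HBD at 0.77 ± 0.32.

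The cytotoxic and NK markers were not called in filtered air (median -0.10, 11 of 17 lower, adjusted p = 0.29), with medians of -0.47, 0.26 and -0.08 in the 3 sessions. Without filtered air session 2, which held the array that stood apart, the cytotoxic and NK markers were called (median -0.31, camera adjusted p = 3.45e-05). Array weights were 2.56, 0.43 and 0.65 for filtered air sessions 1, 2 and 3, and so leaned on session 1. With these weights the list was called too (median -0.38, camera adjusted p = 0.000789). Among the cytotoxic and NK markers, PRF1, the pore-forming protein perforin, stood at -0.59 ± 0.13, S1PR5 at -0.68 ± 0.21 and TBX21 at -0.36 ± 0.11. Adjusted over the list alone, 1 cytotoxic member passed (PRF1, adjusted p = 0.0261) and 1 erythroid member passed (HBB, 0.00339), against 0 adjusted over all genes.

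Over all tested probe sets, 28.64% went the same way in the 3 filtered air sessions, where chance gives 25%. The genes named in filtered air did so by the rule, and had a limma adjusted p of 0.58 each. HBB was highest by another of its probe sets, at 1.24 ± 0.23, followed by HBD, the T cell costimulator ICOS at 0.70 ± 0.26, EIF1B-AS1, EGFR and ADTRP at 0.60 ± 0.12. TFAM, CROCC, VPREB3, MS4A1, ABCD2 and UCA1 lay between 0.51 and 0.56. The lowest were SPEN at -1.19 ± 0.33 and TBL1X at -1.16 ± 0.36, both regulators of transcription, ATXN1 at -1.11 ± 0.25 and CDKN1C at -1.02 ± 0.19, by another of its probe sets than in the particle sessions. The zinc exporter SLC30A1 stood at -0.91 ± 0.13, with -0.96, -0.97 and -0.79 in the 3 sessions, and TIMP2, an inhibitor of matrix proteases, at -0.95 ± 0.17. INPP5D, LINC00537, FGD2, ITGAL, LINC01000 and SYTL3 lay between -1.02 and -0.92, ITGAL by another of its probe sets than that used for the adhesion list. For LINC00537, 1 of 3 tested probe sets had the sign given, for SYTL3 1 of 2 and for TFAM 2 of 4, and TFAM, ABCD2, UCA1 and TBL1X had a group mean below the filter of log2 5.02.

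In filtered air limma called 0 probe sets, and 2317 had an unadjusted p below 0.05, 450 higher and 1867 lower. Chance gives 1363 of independent probe sets. After a second quantile normalization the split was 1011 higher and 1247 lower, after centring on the array medians 234 higher and 2359 lower, and without filtered air session 2, 309 higher and 746 lower. Over all probe sets, with no filter on dim ones, it was 2313 higher and 2640 lower, so that the excess of lower values lay in the brighter probe sets. Without filtered air session 3 the number below 0.05 was 3918. The directional test of fry called 0 of the 4 lists (adjusted p between 0.50 and 0.58).

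Without filtered air session 2, 12 lists were called in filtered air instead of 4. Besides the cytotoxic and NK markers, the lists called without that session but not with it were T cell markers (median 0.15, adjusted p = 0.000113), dendritic cell markers (-0.43, 2.23e-06), NRF2 antioxidant (-0.17, 0.0107), unfolded protein response (-0.11, 0.028), NF-kB inflammation (-0.17, 0.0105) and proliferation (-0.24, 0.00349). Glucocorticoid-induced genes went from -0.01 to 0.11 (adjusted p = 0.0271) and platelet markers from 0.10 to -0.15 (adjusted p = 0.0331), each called in the direction opposite to that in all 3 sessions. Without filtered air session 3 the platelet markers were called in the other direction (median 0.30, adjusted p = 0.000207).

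**Figure D2:**
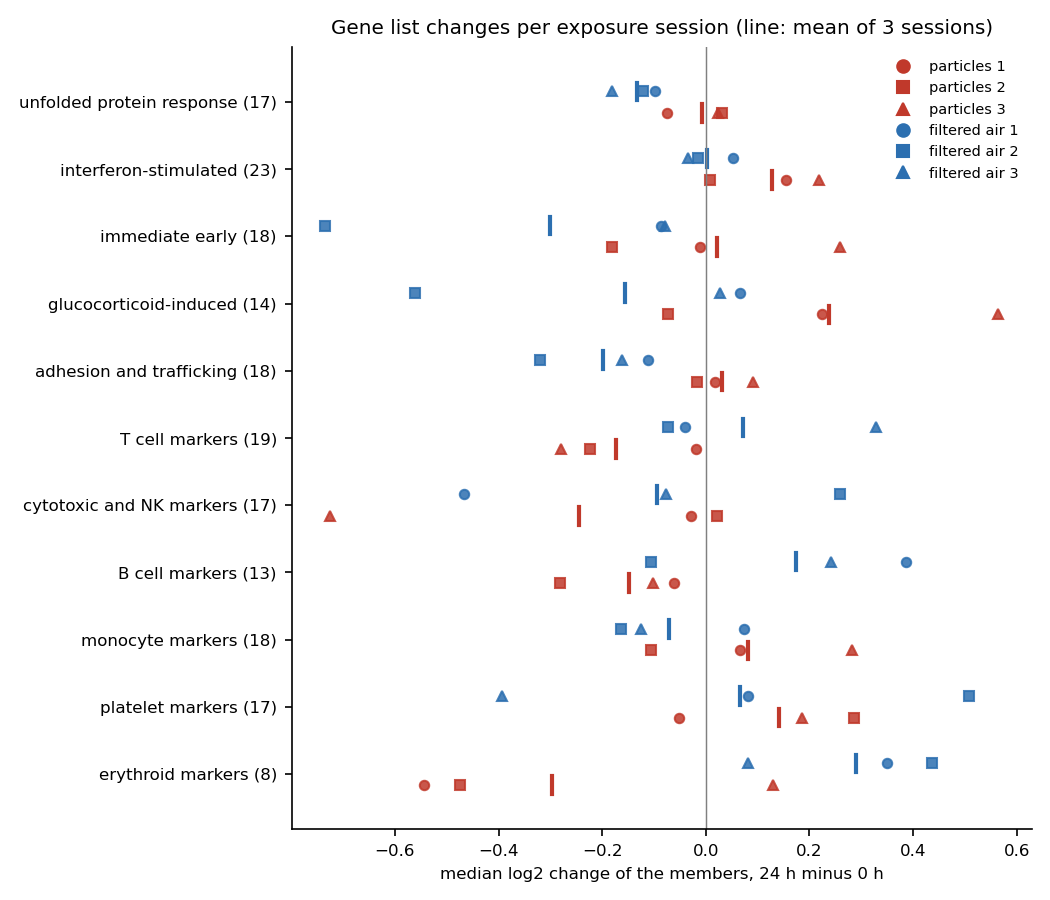
The horizontal axis is the median log2 change (24 h minus 0 h) of a list's tested members in 1 session, for the 11 lists called in any comparison, with the number of members in parentheses; points are sessions (red particles, blue filtered air, shape for the number) and lines are means of 3 sessions. The erythroid medians are -0.54, -0.47 and 0.13 in the particle sessions and 0.35, 0.44 and 0.08 in the filtered air sessions.

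The third comparison asked whether the change over 24 h differed between particles and filtered air, by a test of the difference itself. The change of immediate early and adhesion transcripts was higher with particles than with filtered air, and that of T cell, B cell and erythroid transcripts was lower. The erythroid gap between the exposures lay at 0 h more than at 24 h: the median over the members of particles minus filtered air was 0.69 at 0 h and 0.10 at 24 h. None of the 5 lists was called with a correlation estimated per list (adjusted p = 0.66 with an estimated correlation for each). Single genes with large values were ZNF12 and CDKN1C, whose change was higher in each particle session than in each filtered air session, but 0 of 27259 probe sets passed the adjusted test.

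Of 18 immediate early genes 17 had a higher change with particles, with a median difference of 0.33 (adjusted p = 0.00142; adjusted p = 0.66 with an estimated correlation). KLF4 differed by 0.86 ± 0.26, FOSL2 by 0.46 ± 0.20 and EGR1 by 0.93 ± 0.45. Of 18 adhesion and trafficking genes 15 had a higher change with particles, with a median difference of 0.21 (adjusted p = 0.0109; adjusted p = 0.66 with an estimated correlation), with ITGAX at 0.76 ± 0.27 and ITGB2 at 0.61 ± 0.28. Without filtered air session 2 the adjusted p was 0.0537 for the immediate early list, with a median of 0.10, and 0.068 for the adhesion and trafficking list, with a median of 0.18.

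Of 13 B cell markers 12 had a lower change with particles, with a median difference of -0.28 (adjusted p = 8.49e-05; adjusted p = 0.66 with an estimated correlation). VPREB3 differed by -0.85 ± 0.21, CD79A by -0.52 ± 0.22 and TCL1A by -0.40 ± 0.24. Of 19 T cell markers 16 had a lower change with particles, with a median difference of -0.27 (adjusted p = 0.000481; adjusted p = 0.66 with an estimated correlation), with CD3D at -0.31 ± 0.16, CD2 at -0.39 ± 0.20 and CD8B at -0.40 ± 0.23. The T cell medians were -0.02, -0.22 and -0.28 in the particle sessions and -0.04, -0.07 and 0.33 in the filtered air sessions, and without filtered air session 3 the T cell markers had a median difference of -0.15 (adjusted p = 0.20). Without particle session 2 the T cell markers had one of -0.18 and the B cell markers one of -0.17, and without filtered air session 1 the B cell markers had one of -0.16, all still called.

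All 8 erythroid markers had a lower change with particles, with a median difference of -0.66 (adjusted p = 9.06e-08; adjusted p = 0.66 with an estimated correlation). HBB differed by -1.66 ± 0.29, HBD by -1.53 ± 0.45, ALAS2 by -1.10 ± 0.35 and BPGM by -0.48 ± 0.16. The gap between the groups was larger at 0 h: HBB was at 12.76 ± 1.61 in the particle and 10.97 ± 0.57 in the filtered air sessions at 0 h, and at 12.21 ± 1.45 and 12.08 ± 0.90 at 24 h. ALAS2 was at 5.91 ± 1.16 and 4.68 ± 0.23 at 0 h, and at 5.11 ± 0.50 and 4.98 ± 0.16 at 24 h, so that its filtered air means lay below the filter of log2 5.02 and its changes rest on values near the floor. Adjusted over the list alone, 4 erythroid members (HBB, HBD, ALAS2 and BPGM) and 1 B cell member (VPREB3) passed, against 0 adjusted over all genes.

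**Figure D3:**
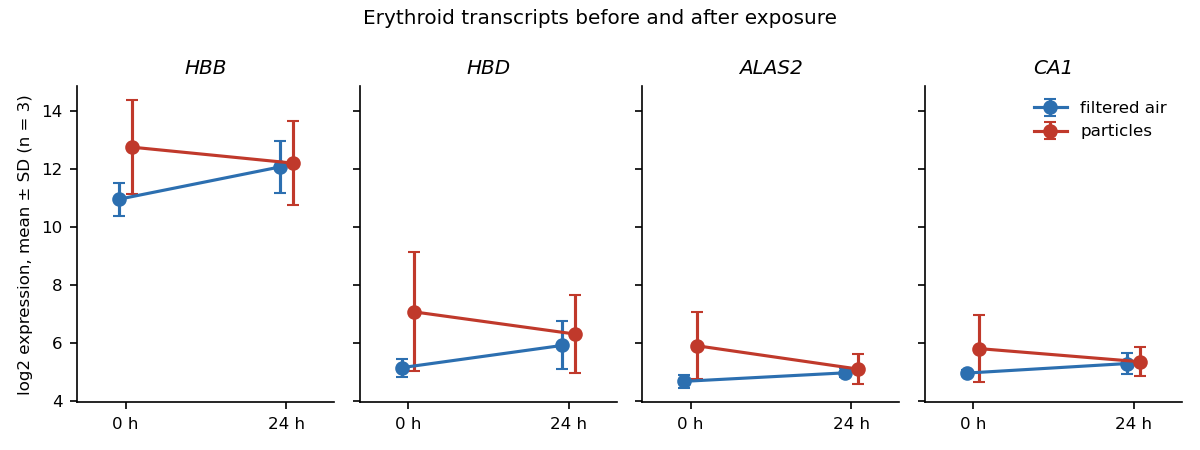
The panels plot log2 expression of HBB, HBD, ALAS2 and CA1 at 0 h and 24 h for filtered air (blue) and particles (red); points are means and bars the SD of 3 arrays. At 0 h the particle groups lie higher than the filtered air groups, by 1.80 for HBB and 1.23 for ALAS2, and at 24 h by 0.13 for each.

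The other lists were not called for the difference. Interferon-stimulated genes had a median difference of 0.15 (17 of 23 higher, adjusted p = 0.0548), the unfolded protein response one of 0.14 (adjusted p = 0.0576), monocyte markers 0.16 (15 of 18 higher, adjusted p = 0.0576), dendritic cell markers 0.28 (8 of 9 higher, adjusted p = 0.0576) and glucocorticoid-induced genes 0.32 (9 of 14 higher, adjusted p = 0.092). Within them, CSF1R, the receptor that sustains monocytes, differed by 0.90 ± 0.22 and XBP1 by 0.84 ± 0.22. Cytotoxic and NK markers had a median difference of -0.11 (adjusted p = 0.18) and platelet markers 0.05 (adjusted p = 0.85), although both lists were called in the particle sessions alone.

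Leaving out 1 session changed several of these calls. Cytotoxic and NK markers were called without filtered air session 1 (median -0.25, adjusted p = 0.00582), particle session 1 (-0.26, 0.0138) or particle session 2 (-0.29, 0.0092), and had a median of 0.08 without filtered air session 2, not called. Platelet markers (0.29, adjusted p = 0.000608), interferon-stimulated genes (0.16, 0.0179) and the unfolded protein response (0.15, 0.013) were called without filtered air session 2. Dendritic cell markers were called without filtered air session 2 (0.41, adjusted p = 2.11e-05) or session 1 (0.47, 0.019). Monocyte markers were called without filtered air session 1 (0.26, adjusted p = 0.00523) or particle session 2 (0.27, 0.00223), and glucocorticoid-induced genes likewise (0.40, 0.019 and 0.46, 0.0092). Interferon-stimulated genes were also called without particle session 2 (0.17, adjusted p = 0.00295), and the unfolded protein response without particle session 1 (0.24, 0.0167).

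With all sessions, 13 lists were called in none of the 3 comparisons of changes. For programs often studied after particle exposure, the median difference was 0.12 for NRF2 antioxidant genes (adjusted p = 0.42), 0.06 for the aryl hydrocarbon receptor (0.94), -0.01 for heat shock (0.94) and 0.13 for NF-kB inflammation (0.23). It was 0.14 for coagulation and fibrinolysis (adjusted p = 0.33), 0.11 for p53 and DNA damage (0.29) and 0.08 for the circadian clock (0.76). It was 0.06 for oxidative phosphorylation (adjusted p = 0.46), -0.01 for ribosomal proteins (0.46), 0.07 for proliferation (0.76), 0.08 for plasma cell markers (0.87) and 0.05 for neutrophil markers (0.76). The 13th, dendritic cell markers, had its lowest adjusted p in this comparison. Single members were PER2, a clock gene, at 0.84 ± 0.27 and the cell cycle inhibitor CDKN1A at 0.70 ± 0.22. Without particle session 1, the aryl hydrocarbon receptor (median 0.19, adjusted p = 0.0379) and coagulation and fibrinolysis (0.29, 0.0164) lists were called in the particle sessions; for the difference, coagulation and fibrinolysis (0.30, 0.0478) and proliferation (0.16, 0.0178) were called without filtered air session 2. The median, mean and test differed in sign for neutrophil markers in all 3 comparisons, for the aryl hydrocarbon receptor and interferon-stimulated lists in filtered air, and for heat shock in the difference.

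Among the genes named for the difference, CDKN1C differed by 1.47 ± 0.27 (adjusted p = 0.62) by the probe set given for filtered air, not that for particles, with -0.05, 0.94 and 0.48 in the particle sessions and -0.80, -0.93 and -1.33 in the filtered air sessions; all 4 of its tested probe sets differed in this direction. ZNF12 differed by 1.41 ± 0.17 (adjusted p = 0.35), and FOLR1, SPEN and TBL1X by 1.44 ± 0.36, 1.74 ± 0.47 and 1.45 ± 0.50. ATXN1, DAPK1-IT1, LINC00537, KIAA0754, AGO2, EHD4 and FYB1 lay between 1.15 and 1.28. HBB was lowest at -1.99 ± 0.34, by a probe set other than the brightest. ADTRP, which regulates the tissue factor pathway inhibitor, differed by -0.97 ± 0.18 and ING3, a histone reader, by -1.05 ± 0.20. GVINP1, ANKRD42-DT, CLN6, VPREB3, SNRNP40, EIF1B-AS1, CD200, GNLY and SCFD1 lay between -1.19 and -0.78. For GVINP1 and SCFD1, 1 of 2 tested probe sets had this sign, and GVINP1 and TBL1X had a group mean below the filter of log2 5.02.

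**Figure D4:**
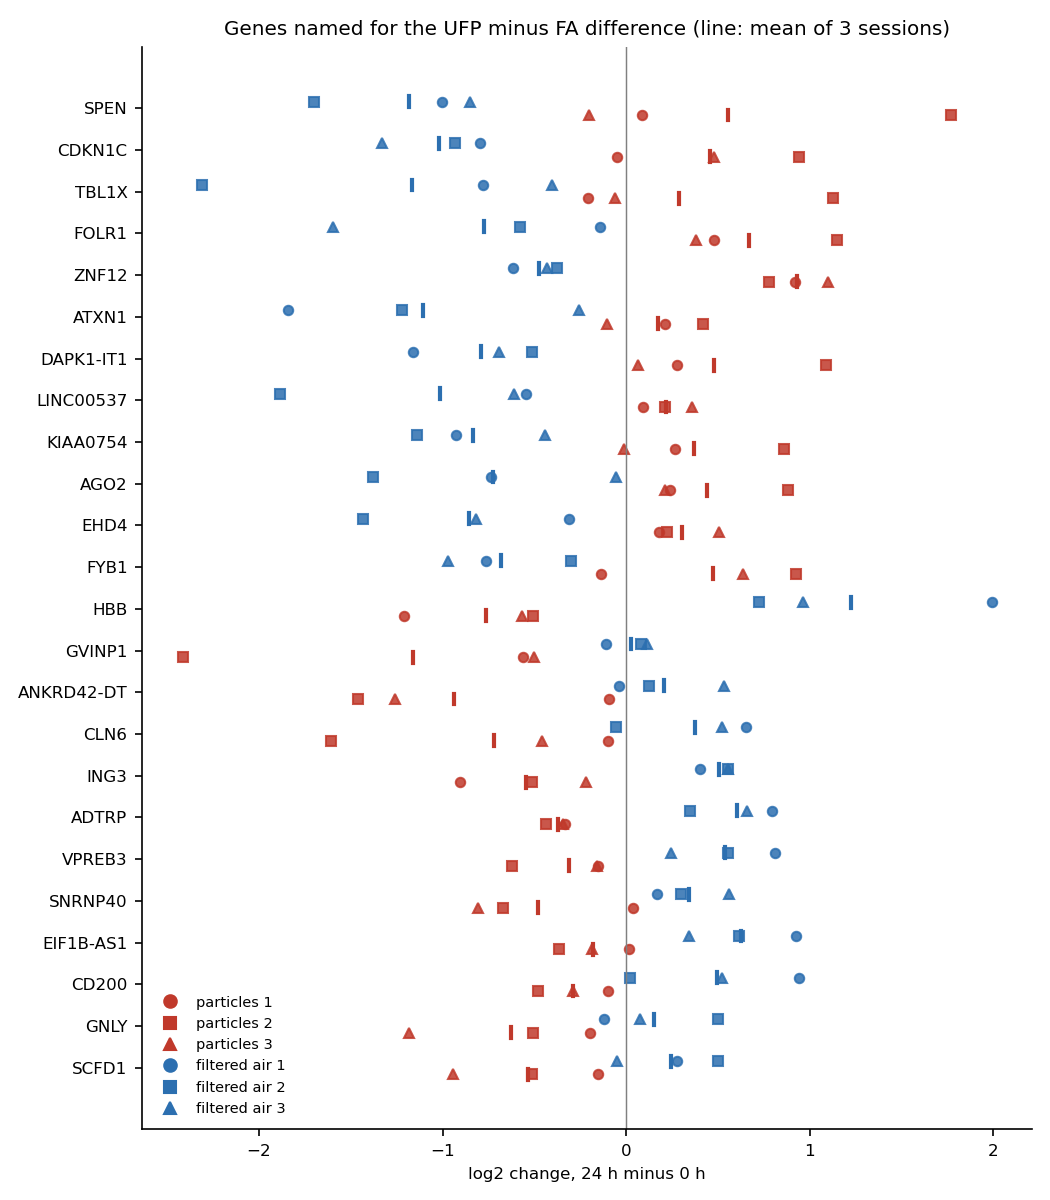
The horizontal axis is the log2 change (24 h minus 0 h) of each gene named for the difference; points are sessions (red particles, blue filtered air, shape for the number) and lines are means of 3 sessions. For each gene the 3 particle changes lie on one side of the 3 filtered air changes, which was a condition of the choice, and none passed the adjusted test.

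For the difference of changes limma called 0 probe sets, and 1471 had an unadjusted p below 0.05, 1110 higher and 361 lower. Chance gives 1363 of independent probe sets. The split was 781 higher and 656 lower after a second quantile normalization, and 1325 higher and 227 lower after centring on the array medians; over all probe sets with no filter it was 1708 higher and 1277 lower, and without filtered air session 3 it was 1888 and 423. The directional test of fry called 0 of the 5 lists (adjusted p between 0.53 and 0.58), and 9 lists were called without filtered air session 1, filtered air session 2 or particle session 2. All 3 particle changes lay on one side of all 3 filtered air changes for 11.04% of probe sets, where chance gives 10%.

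The last comparisons set the particle against the filtered air groups at each time. All 3 arrays of a group lay on one side of all 3 of the other for 4.67% of tested probe sets at 0 h and 4.91% at 24 h. Chance gives 10%, and the genes named here did so by the rule. Those named at 0 h had a limma adjusted p of 0.999992 each. In the particle groups the values were higher for ADTRP (1.29 ± 0.24), ERCC6L2-AS1, GPM6A, MYZAP and CLN6. They were lower for KLRC3, an NK cell receptor (-1.27 ± 0.46), CDKN1C (-0.90 ± 0.24), TGIF2, LOC101928343 and PACSIN1. At 24 h ZNF12 was higher (1.34 ± 0.18, limma adjusted p = 0.21). The other genes named at 24 h had a limma adjusted p of 0.9998 each. Of these, RTN1 (1.17 ± 0.28), TRIM13, MYZAP and NDFIP1 were higher and GNLY (-1.06 ± 0.31), PPAT, ZNF519, LRRC8B and CPA5 lower. For TRIM13, 2 of 4 tested probe sets had this sign, and ERCC6L2-AS1, GPM6A, ZNF519 and CPA5 had a group mean below the filter. The 0 h gap lay on the opposite side from the difference of changes for 8 of the 10 genes named at 0 h and for 23 of the 24 genes named for the difference, and for 12 of these 24 it was larger than the gap at 24 h. A difference of changes subtracts the 0 h gap, so that such opposite signs arise in part from the choice of genes.

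At 0 h limma called 0 probe sets, and 216 had an unadjusted p below 0.05 (117 higher, 99 lower). Chance gives 1363 of independent probe sets at either time. At 24 h limma called 0, and 565 had an unadjusted p below 0.05 (430 higher, 135 lower). The split at 24 h became 260 and 208 after a second quantile normalization and 617 and 75 after centring on the array medians. Over all probe sets, with no filter, the majority turned, with 703 higher and 898 lower. The number below 0.05 at 0 h was 424, 332 and 598 without filtered air session 1, filtered air session 2 and particle session 1, and at 24 h it lay between 239 without particle session 3 and 1414 without particle session 1, with 1354, 278 and 1237 without filtered air sessions 1, 2 and 3. Without particle session 1, limma called 4 probe sets at 24 h. Of these, 3 named MYL4 (1.45, 1.90 and 1.58 higher with particles) and 1 named several genes or none. MYL4 was named after its values were seen. A limma fit with a replicate block by number across exposures called 1 probe set at 24 h, that of ZNF12 (1.34, adjusted p = 0.045). In that fit 1330 had an unadjusted p below 0.05.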

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

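The tests of red cell carry-over, of RNA degradation in a single array, of a single particle session and of a lower share of all lymphocytes were chosen after the results were seen, as was the requirement that a value pass its bound by more than its spread.

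The change of 5 gene lists differed between particles and filtered air by the test of the difference itself, and none of the 5 passed with an estimated correlation (adjusted p = 0.66 each). The median differences were 0.33 for immediate early genes, 0.21 for adhesion and trafficking, -0.27 for T cell markers, -0.28 for B cell markers and -0.66 for erythroid markers. Of the 10 splits of the 6 sessions into sets of 3, which are too few for a share under 0.05, 8 shifted at least 5 lists; the real split shifted 5 and the highest of the others 10.

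By camera at its preset correlation, erythroid transcripts fell between 0 h and 24 h with particles and rose with filtered air. Neither call held with an estimated correlation (camera adjusted p = 0.57 and 0.79), and the list median in particle session 3 was 0.13. With the actin 3'/5' difference as a covariate, the median difference of the list stayed at -0.67. The mean change of the actin measure was much alike in both exposures, so the covariate could move this value little. This test therefore does not decide on RNA quality, which actin alone stood for. A varying carry-over of red cells into the mononuclear fraction cannot be told apart from a change in circulating reticulocytes: the members other than globins had a median difference of -0.51, but they belong to the list that showed the pattern, and 3 of 8 members (ALAS2, AHSP and CA1) had a group mean below the filter. Baseline imbalance may also account for it: the list's median difference between particles and filtered air was 0.69 at 0 h and 0.10 at 24 h, so that the difference at 24 h made up -0.15 of the difference of changes. A biological difference between the exposures stays open and was not tested apart from these.

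In filtered air, 80.6% of the tested probe sets with an unadjusted p below 0.05 were lower at 24 h, against 53.3% over all probe sets with no filter on dim ones. RNA degradation of the 24 h array of filtered air session 2 was argued against, since its actin 3' minus 5' difference of log2 3.54 lay within 3.29 to 4.06, the range of the arrays numbered 2 and 3. A compressed intensity scale on some arrays stays open: a second quantile normalization brought the lower share to 55.2%, but equal distributions balance higher and lower values by construction, and centring on the array medians moved it to 91.0%. Whether that session alone accounts for it could not be settled: without it the lower share was 70.7%, above a bound of 70 by less than the SD of 2.58 of the shares without each other session. An effect of exercise or mouthpiece stays open as well, as no unexposed group was sampled. Time of day has less room, since the samples of a session were labelled 0 h and 24 h, but it was not tested.

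After particles, lymphocyte markers fell and monocyte markers rose by camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.57 to 0.60) nor by fry (adjusted p = 0.87). A single session may account for most of this, since without particle session 3 only 1 of the 4 lists (B cell markers) kept its call. A lower share of all lymphocytes cannot be told apart from separate changes of each type: in particle session 3 the cytotoxic median was -0.72 and the B cell median -0.10, a gap of 0.62, above the bound of 0.5 by less than its bootstrap standard error of 0.17. A change in cell composition due to particles and a change of expression per cell stay open; cell counts were not used here.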

How the results depend on the processing

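The fits of sessions numbered 2 and 3 only and with the actin 3'/5' difference as a covariate were chosen after the data were seen; all other alternatives were planned. No list called with all sessions and no named gene reversed its direction; without filtered air session 2, glucocorticoid-induced genes (median 0.11, adjusted p = 0.0271) and platelet markers (-0.15, 0.0331) in filtered air were called in a reversed direction, and the cause was not tested. Over the sessions left out, the adjusted p of these lists ranged from 0.0271 to 0.887 and from 0.000207 to 0.370. Of 1080 list values under the alternatives 71 differed in direction, 2 of them called. Among the values of lists under the alternatives, 1153 stayed on their side of the threshold, 66 passed it only there and 75 lost their call, and among those of named genes 1469 stayed and 2 passed only there. With an estimated correlation and with fry, the number of called lists fell to 0. It had been 10 for particles, 4 for filtered air and 5 for the difference. The run with an estimated correlation changed only that setting of camera, so these calls depend on the preset correlation of 0.01. For fry the cause was not tested. Called lists of the difference numbered 9 with arrays centred on their medians, 11 without a filter, 8 with an intensity trend, 8 with the probe set of the largest spread per gene and 9 with sessions numbered 2 and 3 only, and those of filtered air numbered 10 without a filter; the cause was not tested. Leaving out each session in turn gave 4 to 11 lists for particles, 3 to 12 for filtered air and 4 to 9 for the difference, 0 to 4 probe sets for particles against filtered air at 24 h, and 0 probe sets in the other comparisons. Array weights gave 3 probe sets for the difference: that of ZNF12 (1.54) and 2 that named several genes or none (-2.60 and -2.77). With array weights, unadjusted p values below 0.05 numbered 1537 for particles, 4141 for filtered air, 2790 for the difference and 1050 at 0 h. At an unadjusted p below 0.05 and at least 1.5-fold, the counts were 77 for particles, 431 for filtered air, 742 for the difference, 82 at 0 h and 210 at 24 h, a looser threshold by construction. Across exposures the arrays of a number correlated at 0.65, 0.40 and 0.30 at 0 h and at 0.40, -0.01 and 0.23 at 24 h. Among all arrays outside their own group and session, 7 of 12 arrays matched one of their own number best. These candidates included arrays of the same exposure, which could not share the number. The count therefore does not settle whether the number pairs arrays across exposures. A replicate block by number across exposures gave 1 probe set at 24 h (ZNF12, 1.34, adjusted p = 0.045), and 0 for the difference and at 0 h, with 1330, 1529 and 557 unadjusted p values below 0.05; without the replicate block, all counts of probe sets in the paired comparisons were 0 and unadjusted p values below 0.05 numbered 75, 563 and 328. Erythroid calls held in 16 of 18 alternatives in each comparison, and the interferon-stimulated, T cell, cytotoxic and platelet calls after particles in 15 of 18; the unfolded protein response held in 9 of 18. The brightest 25% of probe sets ended the particle calls of the unfolded protein response, immediate early, glucocorticoid-induced and B cell lists and the adhesion call of the difference, and array weights ended that call and both filtered air falls. A second quantile normalization ended the unfolded protein response call (adjusted p = 0.0653), and the probe set of the largest spread that call, the B cell call after particles and both adhesion calls. Sessions numbered 2 and 3 only ended the call of monocyte markers after particles, with a larger median (0.15 against 0.08, adjusted p = 0.0843), and of B cell markers in filtered air (0.07 against 0.19, adjusted p = 0.216). The actin covariate ended the immediate early call in filtered air (adjusted p = 0.0557) at a like median (-0.25 against -0.26). Removing the replicate block ended the interferon-stimulated and B cell calls after particles (adjusted p = 0.0709 for each). Array weights moved medians of lists that stayed called by over 1.5 times: after particles the cytotoxic and NK markers to -0.38, monocyte markers to 0.16, immediate early to 0.14, glucocorticoid-induced to 0.29 and unfolded protein response to 0.04, B cell markers in filtered air to 0.30, and the immediate early difference to 0.18. The brightest 25% moved the erythroid markers to 0.65 in filtered air and -1.07 for the difference. Sessions numbered 2 and 3 only moved the interferon-stimulated (0.15), immediate early (0.14), B cell markers (-0.17) and platelet markers (0.28) medians after particles, and adhesion and trafficking (0.34) and B cell markers (-0.16) for the difference. Signal over background limits dim probe sets: the filter acted on the mean of 12 arrays, and 13 of 92 values of named genes came from probe sets with a group mean below it.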

Other observations

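The tests of non-classical monocyte, HLA class II, proteasome and splicing lists were chosen after values had been seen, the first because of the values of CDKN1C; the counts of other splits were planned.

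Antigen presentation genes of HLA class II had a higher change with particles than with filtered air, with a median difference of 0.23 and 8 of 9 members higher (camera adjusted p = 0.0262 over the 4 added lists and 0.048 over all 28 lists; adjusted p = 0.54 with an estimated correlation). The invariant chain CD74 differed by 0.56 ± 0.24 and CIITA, the master regulator of these genes, by 0.57 ± 0.27. The HLA class II medians were 0.27, -0.003 and 0.05 in particle sessions 1, 2 and 3, so that the rise lay mostly in session 1. They were -0.01, -0.14 and -0.26 in the filtered air sessions. The added lists were not tested with a session left out. Proteasome subunits (median difference 0.04, adjusted p = 0.75) and splicing factors (0.05, adjusted p = 0.75) did not pass. A change in non-classical monocytes that differed between particles and filtered air may account for part of the values of CDKN1C, a transcript of that subset, but not in every session: its listed markers other than CDKN1C had a median difference of 0.23, with 8 of 11 higher (adjusted p = 0.0262 over the 4 added lists and 0.048 over all 28 lists; adjusted p = 0.53 with an estimated correlation). SIGLEC10 differed by 0.69 ± 0.16 and MTSS1 by 0.48 ± 0.16. The medians were 0.06, 0.04 and 0.05 in the particle sessions and -0.33, 0.01 and -0.36 in the filtered air sessions, and in filtered air the list was lower at 24 h (median -0.16, adjusted p = 0.0291 over the 4 and 0.0407 over the 28; adjusted p = 0.45 with an estimated correlation). CX3CR1, which the adhesion list also held, differed by -0.03 ± 0.21. In filtered air sessions 1 and 3 CDKN1C was lower along with the marker medians, at -0.80 and -1.33. In filtered air session 2 it stood at -0.93 against a marker median of 0.01. In particle sessions 2 and 3 it stood at 0.94 and 0.48 against marker medians of 0.04 and 0.05. The marker medians thus did not follow CDKN1C in these sessions.

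For the changes within particles or within filtered air, the 4 ways of swapping the times in sessions are too few for a share under 0.05. With particles 1 of the 4 called as many lists, the real one with 10 against 5 at most in the others. In filtered air 4 of the 4 did, the real one with 4 and the highest other with 9. For probe sets all 4 called as many in each, with 0 in the real one and 0 in the others. By unadjusted p below 0.05 the real particle labelling had the fewest probe sets. It had 505, against 1517, 1049 and 534 with the times swapped in particle sessions 1, 2 and 3. In filtered air the counts were 2317 in the real labelling and 834, 917 and 2738 with the times swapped in sessions 1, 2 and 3.

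For comparisons between exposures the 10 splits of 6 sessions are again too few for a share under 0.05. For the difference of changes 10 of 10 called as many probe sets, with 0 in the real split and 0 in the others. At 0 h 10 of 10 called as many, with 0 in the real split and 15 in the highest other, and at 24 h 10 of 10, with 0 in the real split and 14 in the highest other. Unadjusted p values below 0.05 numbered 216 at 0 h in the real split, against 207 to 3627 in the others. At 24 h they numbered 565, against 769 to 5734. The splits that called any were the 4 that placed both sessions numbered 1 on one side. This points to a structure of the samples that sets the sessions numbered 1 apart. The splits that kept both sessions numbered 2 and both numbered 3 together, but divided those numbered 1, called 0 at either time.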
